A study of Homo sapiens with 7 samples.

How the data were processed

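RNA was measured in 7 libraries of Jurkat cells, a human T-ALL line: 3 labelled as a triple knockout of BEX1, BEX2 and BEX5, 2 as electroporated wild type and 2 as wild type. Per the labels, RNA was extracted with an RNeasy mini kit and libraries were made with the Illumina Stranded mRNA Prep ligation kit, which selects poly(A) RNA. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts and DESeq2 and the genome build hg38, without the role of each tool. Their versions, the strand setting, the handling of reads with several alignments and any filter on genes are not given in the sources used here. The deposited table holds a signal value per gene and library, named as normalised counts by the authors. In each library 100% of the values were whole multiples of 1 step, within a tolerance of 0.001, so whole reads could be recovered as gene counts divided by 1 size factor per library. The table lists 13922 genes, each with at least 10 recovered reads in at least 4 of the 7 libraries, and 390 genes with exactly 4. A gene expressed in the 3 knockout libraries alone therefore could not be listed, while 10 listed genes have 0 reads in all 3. No listed gene has 0 reads in either WT library, against 17 to 24 in the other deep libraries, so genes silent in WT may be missing from the table. No mitochondrially encoded gene is listed.

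Recovered reads per library ranged from 3884116 in knockout 3 to 53501085 in WT 2. A floor of 3 reads corresponds to normalised values of 2.56, 2.27 and 21.3 in knockout 1 to 3, 2.06 and 2.18 in electroporated 1 and 2, and 2.42 and 1.62 in WT 1 and 2. Where a group had 0 reads for a named gene, the fold is a lower bound against 3 reads over the group. With 1 to 3 reads the ratio is given with a 95% exact Poisson interval on the reads of the low group. Both cover counting error only. Pairs of libraries within a group were checked for duplicates: differences in reads exceeded Poisson sampling, with a chi-square per degree of freedom of 4.96 to 165, so none of the 5 pairs is a resampled copy.

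Groups, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. Values were tested as log2(value + 1) with limma and a mean-variance trend on 13864 genes with a value of at least 10 in at least 2 libraries, at a Benjamini-Hochberg adjusted p under 0.05. The knockout was compared with all 4 unedited libraries in a fit of 2 groups, and with electroporated and WT cells separately in a fit of 3 groups, which also gave electroporated against WT. A gene changed against both controls passed both tests with the same sign. Of 35 gene lists fixed in advance, the 33 with at least 3 tested genes were tested with camera at its preset correlation of 0.01 and with an estimated correlation. A list was described when it passed or when at least 3 members passed over all genes. The 2 lists not tested were the other BEX genes and the mitochondrially encoded genes. Some lists were only partly covered, with 14 of 37 neuronal, 6 of 12 T-cell receptor and CD3, and 17 of 31 Xq22 names listed. Of 40 histone names, which include older names of the same genes, 10 were listed. Markers of 5 other cell types were fixed too, and 3 had enough tested genes. Gene spans on hg38 came from RefSeq, which held 13426 (96.4%) of the listed genes.

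Named genes were BEX1 to BEX5, then the 12 with the largest log2FC up and the 12 down among genes that passed in the knockout against all unedited cells. These needed a mean of at least 50 in the higher group, 3 knockout values on 1 side of the 4 unedited ones and the same sign against each control. For electroporated against WT the rule took 6 up and 6 down. In each described list up to 4 members with the smallest p could be named. Numbered, clone-based and LOC or LINC names were left out.

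The tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were tried on simulated data built on these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In the knockout against all unedited cells limma recovered 72% of the 2-fold and 94% of the 4-fold genes, with 4.05% false calls. For electroporated against WT it recovered 51% and 89%, with 4.76% false calls. False calls were 5.37% against electroporated cells, 6.88% against WT and 1.43% against both. Changed genes were drawn from the more abundant ones, and all other genes had the same mean in every group. In the data the unedited groups differ and far more genes change, so these rates may not hold there. In a simulation with 3 lists shifted by 0.5 on the log2 scale camera called these 3 and 0 others. Genes were drawn independently of each other there, so it does not test whether the preset correlation is high enough.

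Alternatives chosen at that point were pseudocounts of 0.5 and 5, no filter, a minimum of 50, TMM and same-total scaling, limma without a trend, edgeR and DESeq2 on recovered reads, each library left out in turn, fits of 2 groups alone, 3-group contrasts for the first comparison, averaged control pairs, a 2-fold minimum, a block for the word bis, and an estimated correlation for lists. Added after seeing the data were thinning of each library to the reads of knockout 3, a fit without abundant genes that vary over 4-fold within a group, and list tests under same-total scaling. Called on recovered reads, the first comparison gave 3102 genes by edgeR and 3938 by DESeq2. No base-level data were available, so the edits were not examined, and transcript isoforms were not resolved.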

Results

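Bulk RNA-seq was run on Jurkat cells, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line. The series title concerns ectopic expression of BEX genes in T-ALL, and the labels set edited cells against unedited ones. BEX genes are small X-linked genes at Xq22 first described for their expression in brain. The 7 libraries form 3 groups: 3 libraries of cells labelled as a triple knockout of BEX1, BEX2 and BEX5, 2 of electroporated wild-type cells and 2 of wild-type cells (WT). The last 4 libraries are called unedited here. Reads assigned to the listed genes came to 31499075, 36094523 and 3884116 in knockout libraries 1 to 3, 41011606 and 41697391 in the electroporated libraries, and 36470374 and 53501085 in WT 1 and 2. A gene with 3 reads had a normalised read count of 21.3 in knockout 3 and of 1.62 to 2.56 in the other 6 libraries, and these floors cover counting error only. The titles give each knockout library its own short code and each unedited pair 1 shared code, without saying whether these are clones. A difference in clone or culture history therefore cannot be told from the knockout in any comparison with unedited cells here. Nothing in the labels says that the libraries came from separate cultures, so each p-value measures the spread between these samples, which may be technical in part. Group values are means ± SD over 3 knockout, 4 unedited, 2 electroporated or 2 WT libraries, and log2 fold changes (log2FC) are on the scale of log2(value + 1).

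The first principal component of 13864 genes held 58.5% of the variance and set the 3 knockout libraries (-72.43 to -55.19) apart from the 4 unedited ones (35.73 to 66.45). The second component held 15.8% and set the shallow library, knockout 3, at -55.36. The median SD of a gene within a group was 0.139 on the log2 scale among the knockout libraries, 0.0864 among the WT and 0.25 among the electroporated libraries. Electroporated 2 was closer to both WT libraries (Spearman rho across genes 0.985 with each) than to electroporated 1 (0.977). Genes within a library are not independent replicates.

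The first comparison asks what became of the targeted genes themselves. BEX1 mRNA was much lower in the knockout cells, BEX2 mRNA was not measurably changed, and BEX5 mRNA was higher. BEX1 (chromosome X, 103062651 to 103064171) had 420.1 ± 21.1 normalised counts in the knockout and 2264 ± 412 in the unedited cells, a log2FC of -2.41 with a standard error (SE) of 0.15 (limma, Benjamini-Hochberg adjusted p = 0.000108). All 3 knockout values, 404 to 444, lay below all 4 unedited values, 1835 to 2671. BEX2 (chromosome X, 103309346 to 103310990) had 277 ± 74.4 in the knockout and 394 ± 129 in the unedited cells (log2FC -0.47, SE 0.33, adjusted p = 0.33), and the groups overlapped. BEX5 (chromosome X, 102153712 to 102155977) had 204 ± 123 against 47.2 ± 11.6 (log2FC 1.96, SE 0.41, adjusted p = 0.0109), with each knockout value above each unedited one. Against the electroporated cells alone BEX5 passed as well (adjusted p = 0.0171), whereas against WT alone it did not (0.0513). An mRNA level does not report whether a reading frame is intact, and the edits themselves cannot be seen in gene counts.

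The BEX relatives that were not targeted did not pass in the knockout against all unedited cells. BEX3 (chromosome X, 103376323 to 103378164) had 3235 ± 154 in the knockout and 2647 ± 379 in the unedited cells (log2FC 0.30, adjusted p = 0.106), and its adjusted p was 0.00857 against the electroporated cells and 0.376 against WT. With each library rescaled to the same total, the BEX3 log2FC was 0.40 (adjusted p = 0.0461), and in the fit of 3 groups against the mean of both controls its adjusted p was 0.0215. BEX4 (chromosome X, 103215092 to 103217246) had 466 ± 113 against 523 ± 202 (log2FC -0.10, adjusted p = 0.865), and its log2FC was 0.00 under the same-total scaling.

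**Figure D1:**
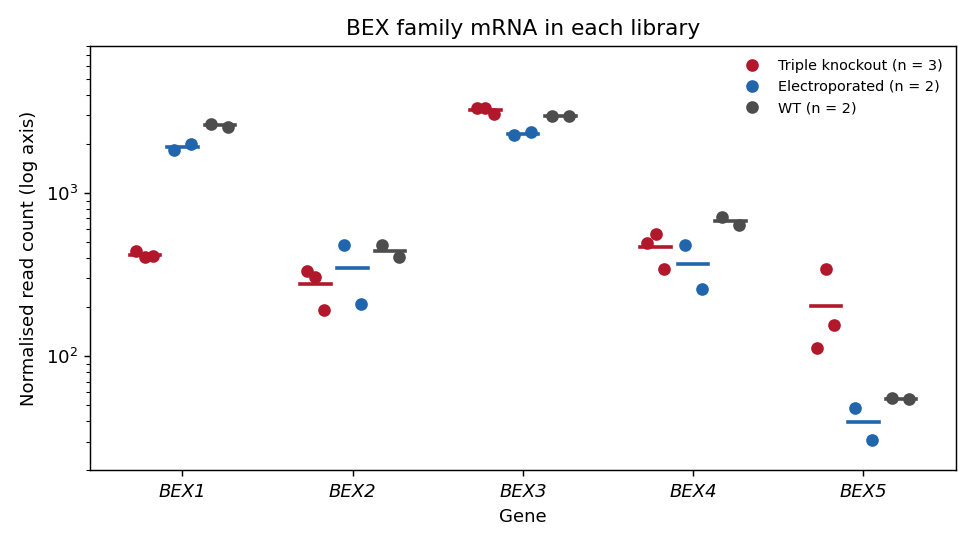
Normalised read counts (log axis) of BEX1 to BEX5 in each of the 7 libraries, with 1 point per library and a bar at each group mean. BEX1 lies between 404 and 444 in the knockout libraries and between 1835 and 2671 in the unedited ones, while BEX5 is higher in each knockout library than in each unedited one.

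Around the BEX genes on Xq22, 4 of 17 tested neighbours rose in the knockout and 1 fell (4 and 1 adjusted over the list alone), and the list as a set did not pass (camera, adjusted p = 0.57). TMSB15A, which encodes a thymosin beta, rose from 565 to 1748 (log2FC 1.67, adjusted p = 0.00138), and ARMCX4 rose by 2.36 (adjusted p = 0.00717). ZMAT1 fell by 1.63 on the log2 scale (adjusted p = 0.0104). TCEAL4 rose by 3.04 (adjusted p = 0.0194), a call that was lost without knockout 1 (0.0754) or knockout 2 (0.0709). The median log2FC of the 17 neighbours was 0.15, and it was -0.06 in the 3-group fit against WT alone.

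Across the transcriptome, the knockout cells had far less mRNA of several T-cell surface molecules and signalling genes, and less mRNA of cholesterol synthesis, ribosome biogenesis and unfolded protein response genes. Several transcription factors of the T-ALL literature, some Notch pathway genes and several neuronal genes were higher, while MYC and PTCRA of the Notch gene list were lower. Gene lists passed as sets only at the preset correlation of the test, and 0 did with an estimated correlation. CD2, the adhesion receptor for CD58, had 144 ± 45.9 normalised counts in the knockout and 2785 ± 902 in the unedited cells (log2FC -4.25, adjusted p = 0.000126). CAMK4, a calcium/calmodulin-dependent kinase, fell from 5653 ± 548 to 58.7 ± 20.96 (log2FC -6.61, SE 0.21, adjusted p = 2.56e-06). KLF2, a transcription factor of T-cell quiescence and trafficking, rose from 329 ± 104 to 1698 ± 60.6 (log2FC 2.42, adjusted p = 0.000403).

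In numbers, 3087 of 13864 tested genes passed in the knockout against all unedited cells (limma, Benjamini-Hochberg adjusted p under 0.05), 1751 higher and 1336 lower, against 5055 at an unadjusted p under 0.05. Of the 3087, 1314 changed at least 2-fold, 960 higher and 354 lower. All 3087 had the same sign against each control group, which passing against both groups pooled makes likely beforehand. In 3042 the 3 knockout values lay outside the range of the 4 unedited ones. Over all tested genes 36.0% were apart in this way, where chance gives 5.71%. The share of higher genes was 56.7%, and 70.9% (2216 higher, 909 lower) when each library was rescaled to the same total. The count was 1510 without knockout 1, 1533 without knockout 2, and 4637 without electroporated 1. Among the called genes, electroporated 1 was the unedited library nearest to the knockout mean in 1298 (42.0%), electroporated 2 in 368, WT 1 in 572 and WT 2 in 849. Because each listed gene had at least 10 reads in at least 4 of the 7 libraries, a gene expressed in the 3 knockout libraries alone could not be listed, while a gene silent in all 3 could.

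**Figure D2:**
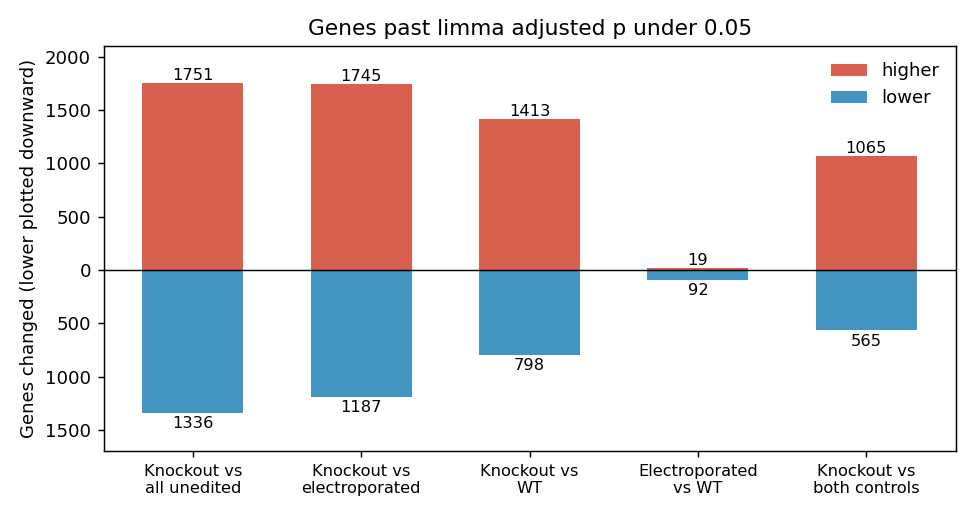
Number of genes past the test (vertical axis, genes) in each comparison and against both controls, with genes higher plotted upward and genes lower plotted downward from 0. The knockout differs from all unedited cells in 3087 genes, from electroporated cells in 2932 and from WT in 2211, and electroporated cells differ from WT in 111.

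The genes that rose most in the knockout, by the rule fixed for naming genes, were low or absent in the unedited cells. KCNQ5, a voltage-gated potassium channel subunit (chromosome 6, 72622064 to 73198853), had 601 ± 73.5 in the knockout and 3.47 ± 4.98 in the unedited cells (log2FC 7.71, adjusted p = 0.00047). NPTX1, a neuronal pentraxin (chromosome 17, 80466834 to 80476607), had 868 ± 350.3 against 4.40 ± 4.58 (log2FC 7.62, adjusted p = 0.000304). NKX2-1, a homeobox gene activated in a subset of T-ALL (chromosome 14, 36516397 to 36520232), had 847 ± 499 in the knockout, with over 4-fold variation among these libraries, 0 reads in both electroporated libraries and 21.4 ± 8.63 in WT (adjusted p = 0.00547 against all unedited). Relative to the electroporated cells it was at least 800-fold higher, with a floor of 3 reads over the group. EFHD1, a mitochondrial calcium-binding protein gene, rose from 62.2 ± 59.7 to 4719 ± 583 (log2FC 7.05), LPAR6, a lysophosphatidic acid receptor gene, from 36.2 ± 24.3 to 2614 ± 265 (log2FC 6.34), and MARCKS, a protein kinase C substrate gene, from 53.6 ± 35.8 to 3074 ± 100.1 (log2FC 6.12). The chemokine gene CXCL16 rose by 6.28, IGSF10 by 6.15, RAMP2 by 6.10, FBXL7 by 7.03 and ZNF544 by 7.11, with adjusted p between 0.000732 and 0.00358. FBXL7 and ZNF544 had 0 reads in both electroporated libraries and were at least 374-fold and 550-fold higher than there. The gap to WT was smaller, with means of 6.46 and 17.4 in WT and 396 and 583 in the knockout. IGFBPL1 rose by 6.29 (adjusted p = 0.0187), a call that was lost without knockout 1 (0.0643) or knockout 2 (0.0736). Its mean was 966 in the knockout and 77.8 in WT, with 3 reads over both electroporated libraries. The log2FC of genes with so few reads in the electroporated libraries depends on the pseudocount.

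Among the genes that fell most, several were close to silent in all 3 knockout libraries. BLK, a Src-family kinase gene (chromosome 8, 11494387 to 11564599), had 0 reads in the 3 knockout libraries and 236 ± 60.5 normalised counts in the unedited cells, at least 207-fold lower (adjusted p = 2.63e-05). HSD17B12, an enzyme gene of very-long-chain fatty acid elongation (chromosome 11, 43556721 to 43856615), had 1.54 ± 1.98 against 974 ± 71.1 (log2FC -8.88, adjusted p = 5.16e-05). IFI35, an interferon-induced gene, had 1 read over the 3 knockout libraries, a ratio of 597 between unedited and knockout cells with a 95% counting interval of 107 to 23600. PREX2, a Rac exchange factor gene, had 3 reads and a ratio of 535 (183 to 2590). The zinc finger genes ZNF738 and ZNF69 had 1 and 3 reads, with ratios of 1720 (310 to 68100) and 149 (51.1 to 724). The fitted log2FC of genes with so few reads depends on the pseudocount and is no bound. SOX5 fell by 8.25 on the log2 scale (adjusted p = 0.000532), SLC4A4, a sodium bicarbonate cotransporter gene, fell by 7.52, RAI14 fell by 7.51, CDHR1 fell by 7.12 and RASEF fell by 6.96, with adjusted p between 0.000339 and 0.00122. CDHR1 also varied between libraries of 1 group, with 414 ± 288 in WT. All 24 genes of this rule except IGFBPL1 kept their call in each fit that left out 1 library. Counts of zinc finger genes and other close paralogs depend on how reads with several alignments were handled, which the sources do not give.

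**Figure D3:**
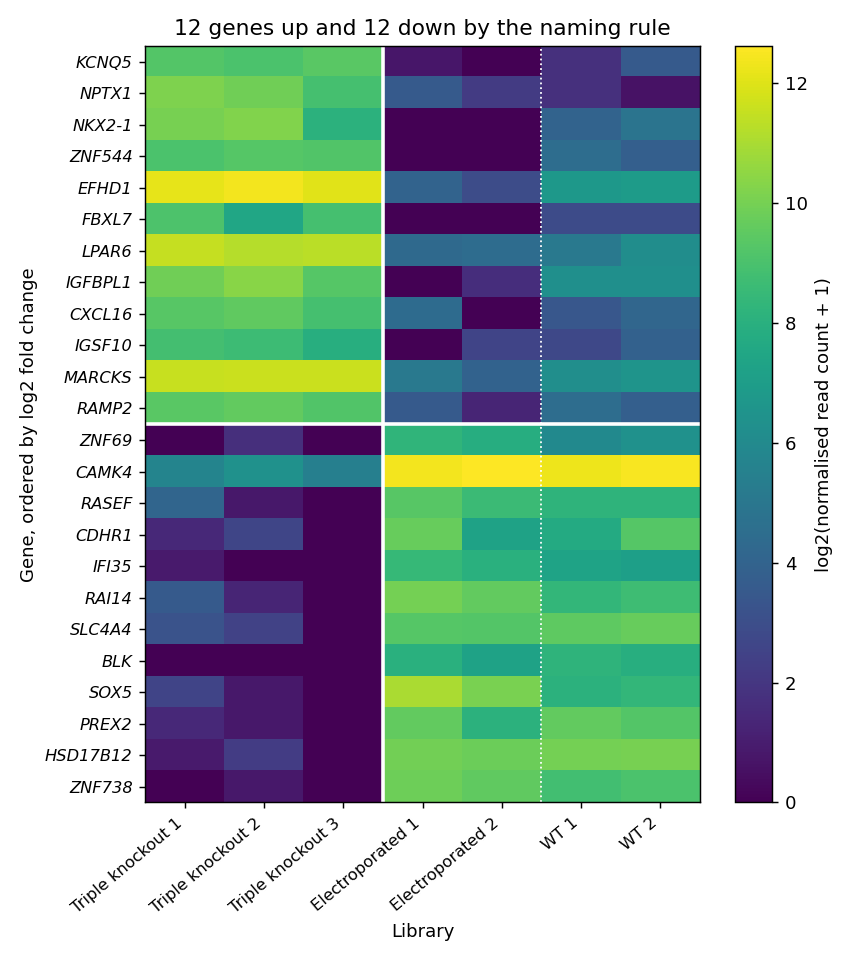
Heat map of log2(normalised read count + 1) of the 24 genes with the largest changes between knockout and unedited cells, 12 higher and 12 lower, with 1 column per library. In each of the 24 genes the 3 knockout values lie on 1 side of the 4 unedited values, as the rule for naming genes required.

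T-cell receptor genes were lower in the knockout. Of 6 tested genes of the receptor and CD3 complex, 4 fell and none rose (5 adjusted over the list alone), and the set passed (camera, adjusted p = 0.045, and adjusted p = 0.768 with an estimated correlation). CD247, the CD3 zeta chain gene, fell from 4765 ± 833 to 2988 ± 230.3 (log2FC -0.66, adjusted p = 0.0104), and CD3D fell by 0.43 on the log2 scale (0.0168). Without knockout 1 neither passed (0.0534 and 0.0869), and without knockout 3 CD3D did not (0.0643). The set lost its call without knockout 1 (0.0586), knockout 3 (0.0731), electroporated 1 (0.0703), electroporated 2 (0.0632), WT 1 (0.0509) or WT 2 (0.0569), and in the 3-group fit against the electroporated cells (0.0509) and against WT (0.0886). Of 37 receptor signalling genes 13 fell and 3 rose (16 and 4 adjusted over the list alone; camera adjusted p = 0.0301, and adjusted p = 0.836 with an estimated correlation). WAS, the Wiskott-Aldrich syndrome gene of actin assembly, fell from 4514 ± 296 to 651 ± 37.1 (log2FC -2.79, adjusted p = 2.56e-06), and the adaptor gene PAG1 fell by 2.90 (0.000811). The phosphatase gene UBASH3B rose by 0.88 (0.000387) and MALT1 by 0.88 (0.00189). This set lost its call without knockout 1 (0.0586) or electroporated 1 (0.178), and against WT in the 3-group fit (0.132).

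T-cell surface molecules changed in both directions, with 7 of 26 lower and 4 higher (9 and 6 adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.293). Besides CD2, the genes of CD5, a negative regulator of receptor signalling, and of the early activation marker CD69 had log2FC of -3.11 and -4.74 (adjusted p = 0.000214 and 0.000263), and CD48 fell by 2.43 (0.00106). Among transcription factors studied in T-ALL 11 of 41 rose and 4 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.145). RUNX3 rose by 1.28 (0.000557) and HHEX by 2.89 (0.00175), while STAT5A, a mediator of cytokine signalling, fell from 1919 ± 324 to 224 ± 142 (log2FC -3.31, 0.00122), with over 4-fold variation among the knockout libraries. Against WT alone in the 3-group fit this set passed (adjusted p = 0.019). Of 18 genes of immature thymocytes 5 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.488). KIT, a stem cell factor receptor gene, rose from 598 ± 73.04 to 2558 ± 830.1 (log2FC 2.05, 0.000725), and LYL1 by 1.85 (0.00744).

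Notch pathway genes were higher as a set, with 10 of 31 up, 4 down and 17 without a call (10 and 5 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.768 with an estimated correlation). NRARP, a Notch target that feeds back on the pathway, rose from 23.6 ± 5.26 to 267 ± 23.4 (log2FC 3.47, adjusted p = 0.000183). HES6 rose by 1.76 (0.000454), HEYL by 1.28 (0.00138) and ADAM10, a protease that cleaves Notch receptors, by 0.82 (0.00103). MYC (0.00479) and PTCRA (0.0325), which are on this list too, fell. PTCRA lost its call in 5 of the 7 fits that left out 1 library. The set lost its call without electroporated 1 (0.0703) and against WT in the 3-group fit (0.205).

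Neuronal and ciliary genes rose as sets, although only 14 of the 37 neuronal genes fixed in advance were listed. Of 14 neuronal genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00549, and adjusted p = 0.768 with an estimated correlation). TUBB3, a neuronal tubulin gene, rose from 282 ± 100 to 2069 ± 30.3 (log2FC 2.94, adjusted p = 0.000333), SYN1, a synaptic vesicle protein gene, by 1.26 (0.00255) and the neurofilament gene NEFM by 1.70 (0.00708). Of 49 primary cilium genes 12 rose and 1 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.00498, and adjusted p = 0.768 with an estimated correlation). SMO, the Hedgehog signal transducer gene, rose by 0.81 (0.00161), the intraflagellar transport gene IFT52 by 0.62 (0.00468) and BBS2 by 0.86 (0.00672). Of 15 genes of neurotrophin receptors and signalling 2 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.937), with a median of -0.00 and a mean of 0.31. NGFR, which encodes the p75 neurotrophin receptor that BEX proteins have been linked to, rose from 16.2 ± 9.16 to 161 ± 47.5 (log2FC 3.32, 0.00149), while SHC1 fell by 1.30 (0.000194).

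Genes of biosynthesis and protein folding fell as sets. Of 28 cholesterol synthesis genes 20 fell and none rose (26 adjusted over the list alone; camera adjusted p = 9.04e-09, and adjusted p = 0.768 with an estimated correlation). HMGCS1, an early enzyme gene of the pathway, fell from 43122 ± 17777 to 8387 ± 1501 (log2FC -2.25, adjusted p = 0.00368), and the log2FC was -1.06 for EBP (0.00188) and -1.01 for SREBF2, which encodes a transcription factor of the pathway (0.00565). Electroporated 2 was the unedited library nearest to the knockout mean in 19 of the 20 called genes. Of 45 MYC target and ribosome biogenesis genes 21 fell and none rose (33 adjusted over the list alone; camera adjusted p = 9.04e-09, and adjusted p = 0.836 with an estimated correlation). The nucleolar genes NOP2 and GNL3 fell, with log2FC of -0.73 and -0.80 (0.0081 and 0.00969), and electroporated 1 was nearest to the knockout mean in 19 of the 21 called genes. MYC itself fell by 0.76, from 12580 ± 1772 to 7375 ± 787 (0.00479).

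Of 25 genes of the unfolded protein response 14 fell and none rose (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.61e-05, and adjusted p = 0.347 with an estimated correlation). SDF2L1 fell by 1.30 (adjusted p = 0.000608), MANF fell by 1.16 (0.00326) and the chaperone gene CALR fell from 41911 ± 2745 to 21882 ± 4832 (0.00339). Of 20 heat shock genes 3 fell (2 adjusted over the list alone; camera adjusted p = 0.045, and adjusted p = 0.836 with an estimated correlation), among them HSPH1 (log2FC -1.48, 0.00407) and CHORDC1 (-3.49, 0.00887). The heat shock set lost its call without knockout 1 (0.123), knockout 2 (0.082), electroporated 2 (0.0632), WT 1 (0.0752) or WT 2 (0.147), and against the electroporated cells in the 3-group fit (0.432). Of 69 nuclear genes of oxidative phosphorylation 3 fell (0 adjusted over the list alone), and the set passed (camera, adjusted p = 0.000801, and adjusted p = 0.836 with an estimated correlation) with a median log2FC of -0.23. The median log2 difference of this list from the WT mean was -0.33 in electroporated 1 and 0.14 in electroporated 2. The 3 called members, NDUFB6, NDUFB7 and NDUFS6, had adjusted p of 0.0382, 0.041 and 0.0485 and kept their call only without electroporated 1 among the fits that left out 1 library, with adjusted p up to 0.17. Of 10 replication-dependent histone genes 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.768 with an estimated correlation), and H2AC11 went from 18.5 ± 6.49 to 1.86 ± 1.63 (adjusted p = 0.0118). Most mRNAs of this group lack a poly(A) tail, the feature that the library kit selects for. The histone set lost its call without electroporated 1 (0.0703) or WT 1 (0.0676).

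The remaining lists did not pass as sets but held at least 3 called genes. Of 46 interferon-stimulated genes 7 rose and 7 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.669), with IFITM2 higher by 1.95 (0.000194), SAMD9L by 2.15 (0.00037) and IFI35 nearly absent. Of 39 adhesion and migration genes 8 rose and 12 fell (10 and 12 adjusted over the list alone; 0.644). The integrin genes ITGAL and ITGB2, which form the receptor LFA-1, fell, with log2FC of -2.35 and -0.79 (0.000339 and 0.000889), its ligand gene ICAM2 fell by 1.06 (0.000432), and another ligand gene, ICAM1, rose by 2.87 (0.000918). Of 39 cytokine, chemokine and receptor genes 5 rose and 9 fell (5 and 11 adjusted over the list alone; 0.335), among them CCR4 (log2FC 2.28, 0.000795), IL2RB (-3.12, 0.000932) and TGFBR2 (-1.44, 0.00131). Of 32 AP-1 and immediate-early genes 7 rose and 3 fell, as they did adjusted over the list alone (0.271), including NR4A1 (log2FC 1.11, 0.00838). Of 28 NF-kB genes 2 rose and 2 fell (1 and 1 adjusted over the list alone; 0.646), ICAM1 among the former, and NFKB1 fell by 0.52 (0.0125), a call lost without knockout 2 (0.0504).

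Cell cycle lists did not pass as sets with all libraries, but both passed as lower without electroporated 1 (G1/S median -0.17, adjusted p = 0.0289; G2/M median -0.15, 0.00654). Of 46 G1/S genes 2 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.938), and the median of -0.03 and the mean of 0.08 differed in sign. CCND2, which encodes cyclin D2, rose from 45.3 ± 26.6 to 903 ± 120.3 (log2FC 4.70, adjusted p = 0.00323). Of 53 G2/M genes 3 fell and none rose (2 and 0 adjusted over the list alone; 0.938), with a median of 0.02 and a mean of -0.00, and G2E3 fell by 0.75 (0.00907). Of 28 p53 targets 4 rose and 3 fell, as they did adjusted over the list alone (0.666), with AEN at a log2FC of -0.72 (0.00433). Of 25 pro-apoptotic and caspase genes 2 rose and 3 fell, again as adjusted over the list alone (0.938). The death receptor gene FAS fell by 1.06 (0.00283), and BOK and APAF1 rose by 2.27 and 0.67 (0.00322 and 0.00664).

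Of 35 glycolysis and hypoxia genes 7 fell and none rose (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.126, and 0.00584 against WT alone in the 3-group fit and 0.037 without electroporated 1). PGK1 fell by 1.27 (0.00374) and ALDOC fell by 3.57 (0.0076). Of 79 cytoplasmic ribosomal protein genes 7 fell and none rose (2 adjusted over the list alone; 0.0632), and the set passed with TMM scaling (0.0487), without knockout 2 (0.00586) or WT 2 (0.01), and against the electroporated cells in the 3-group fit (0.00384). Of 40 mTOR, lysosome and autophagy genes 3 rose and 3 fell (1 and 3 adjusted over the list alone; 0.487), with CTSB higher by 0.75 (0.00476) and CTSD at -0.71 (0.00244). Of 37 chromatin and DNA methylation enzyme genes 4 rose and 3 fell, as they did adjusted over the list alone (0.959). DNMT3B, a de novo DNA methyltransferase gene, rose by 1.05 (0.0046) and TET1 by 0.93 (0.00717), while CREBBP fell by 0.67 (0.0102). In all, 11 of 33 tested lists passed, 3 higher and 8 lower, and 0 passed with an estimated correlation. A further 18 lists held at least 3 called genes, and 4 did neither. These were the 3 targeted genes (1 higher, 1 lower, also adjusted over the list alone; camera adjusted p = 0.585), 12 anti-apoptotic genes (1 higher, also adjusted over the list alone; 0.644), 14 MHC genes (0 and 0; 0.762), and 37 genes of the amino acid and integrated stress response (1 lower, 0 adjusted over the list alone; 0.666).

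**Figure D4:**
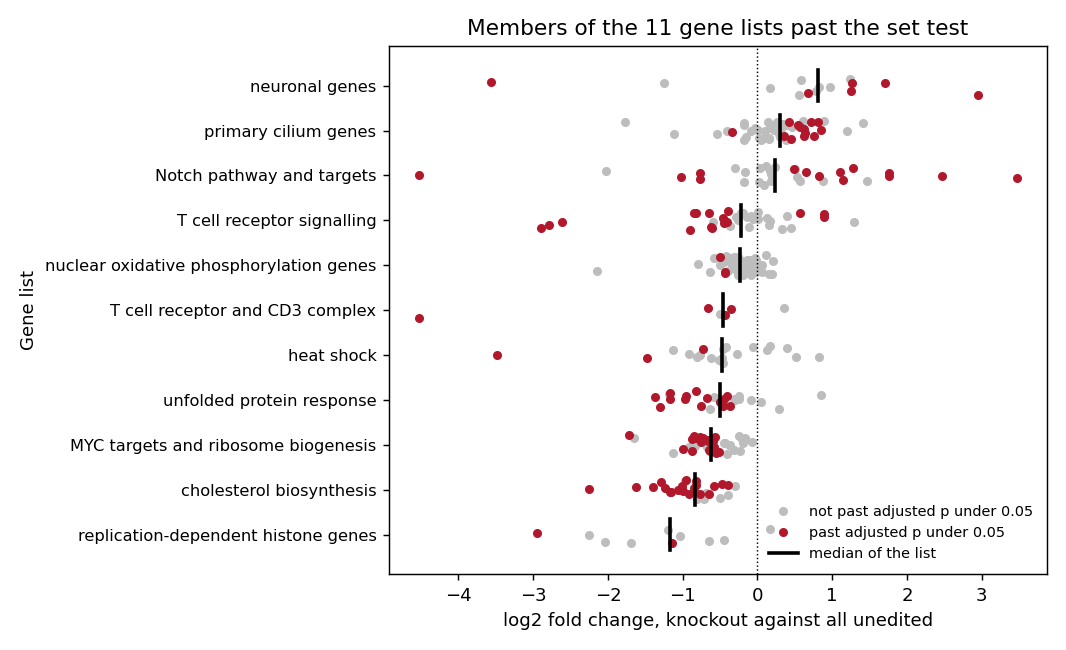
Log2 fold change (horizontal axis) in the knockout against all unedited cells of the members of the 11 gene lists past the camera test, with 1 point per gene, red where the gene passed and grey where it did not, and a bar at each list median. Cholesterol synthesis genes have a median of -0.84 and neuronal genes of 0.81.

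Markers of other blood cells were looked at for RNA of other cells. Only 5 of 12 B cell, 4 of 15 myeloid, 8 of 12 NK and cytotoxic, 2 of 17 erythroid and megakaryocyte, and 2 of 12 fibroblast and epithelial markers were listed, and the last 2 lists had fewer than 3 tested genes. None of the 3 tested lists passed as a set in the knockout against all unedited cells (camera, adjusted p = 0.303 for B cell, 0.303 for myeloid and 0.613 for NK and cytotoxic markers). Single members did: 2 of 5 B cell markers higher (median log2FC 0.88), 1 of 3 myeloid markers higher (0.56), and 1 higher and 1 lower of 8 NK and cytotoxic markers (-0.69), each with the same counts adjusted over the list alone. In the electroporated against WT cells the set adjusted p were 0.146, 0.65 and 0.412. There 1 of 5 B cell markers was lower (3 higher and 1 lower adjusted over the list alone; median 1.12), 0 of 3 myeloid markers passed (0 over the list alone; -0.35), and 1 of 8 NK and cytotoxic markers was higher (1 higher and 1 lower over the list alone; 0.22). So few markers do not exclude RNA of other cells.

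Setting the knockout against each control in turn asks which changes do not rest on 1 of them. CD2, CAMK4 and WAS were lower and TUBB3, MARCKS and LPAR6 higher against electroporated and WT cells alike. CAMK4 had a log2FC of -6.67 against the electroporated cells (adjusted p = 2.6e-05) and of -6.56 against WT (6.51e-05). TUBB3 had 375 and 361 in the 2 electroporated libraries, 195 ± 14.3 in WT and 2069 ± 30.3 in the knockout. Against the electroporated cells 2932 genes passed (1745 higher, 1187 lower), against WT 2211 (1413 higher, 798 lower). With the same sign against both, 1630 passed (1065 higher, 565 lower), and 839 of these changed at least 2-fold against each. Independent lists of these sizes would share 177.8 genes higher and 68.3 lower, and 20 simulations without any difference between groups shared 0, which does not measure the overlap from shared libraries where many genes change. Both comparisons use the same 3 knockout libraries, so part of the excess may come from them.

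These counts depended on single libraries. Against the electroporated cells the count was 1607 without knockout 1, 1613 without knockout 2 and 5354 without electroporated 1. Against WT it was 1052 without knockout 1, 1059 without knockout 2, 4539 without electroporated 1, 4534 without electroporated 2, 519 without WT 1 and 639 without WT 2, and 4550 in a fit of these 2 groups alone. Against both controls it was 790, 776, 3445, 453 and 557 without knockout 1, knockout 2, electroporated 1, WT 1 and WT 2, and 1032 with every library thinned to the reads of knockout 3. Rescaled to the same total, the share of higher genes went from 59.5% to 71.5% against the electroporated cells, from 63.9% to 74.4% against WT, and from 65.3% to 77.0% against both.

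The electroporated cells were set against WT to measure what differs between the unedited groups. A few genes were nearly silent in the electroporated cells, among them CABCOCO1, ALDH1B1 and CD109, and a handful were several times higher, among them EIF3K, ELP5, NPTXR and DAXX. ALDH1B1, a mitochondrial aldehyde dehydrogenase gene (chromosome 9, 38392702 to 38398661), had 2 reads over both electroporated libraries and 341 ± 48.5 normalised counts in WT, a ratio of 483 with a 95% counting interval of 134 to 3990 (limma, adjusted p = 7.09e-05). CABCOCO1 (chromosome 10, 61662929 to 61766766) had 0 reads in the electroporated libraries and was at least 429-fold lower than in WT (0.00178). CD109 had 1 read and a WT to electroporated ratio of 239 (42.9 to 9440), NUDT19 had 2 reads and a ratio of 76.4 (21.1 to 631), and IGFBPL1 had 3 reads and a ratio of 73.4 (25.1 to 356). The protocadherin gene PCDH19 fell from 137 ± 8.59 to 2.81 ± 0.892 (log2FC -5.20, adjusted p = 0.00233).

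Among the genes higher in the electroporated cells, EIF3K, a translation initiation factor subunit gene, had 629 ± 411 against 55.6 ± 2.26 (log2FC 3.30, adjusted p = 0.0459). ELP5 had 420.4 ± 11.97 against 79.01 ± 19.5 (2.42, 0.012) and DAXX 362 ± 12.7 against 73.2 ± 1.31 (2.29, 0.0118). DAXX lies on chromosome 6 between 28 and 34 Mb, where several abundant genes varied over 4-fold between libraries of 1 group, and genes that varied so also lie within 1 Mb of EIF3K and ELP5. NPTXR had a log2FC of 2.33 (0.0127), ENC1 of 1.69 (0.0178) and the perforin gene PRF1 of 1.65 (0.0316). Of these 12 named genes ALDH1B1 alone kept its call in every fit that left out 1 library. CD109 lost its call without WT 2 (0.056), and the other 10 lost theirs without WT 1 and without WT 2, with adjusted p up to 0.328. EIF3K and PRF1 also lost theirs without any 1 of the knockout libraries, and ENC1 without knockout 1 (0.057).

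In numbers, 111 genes passed between electroporated and WT cells, 19 higher and 92 lower, against 1766 at an unadjusted p under 0.05. The count was 40 without knockout 1, 44 without knockout 2, 71 without knockout 3, 404 without electroporated 1, 2009 without electroporated 2, 4 without WT 1 and 2 without WT 2. It was 144 by edgeR and 678 by DESeq2 on the recovered reads, 46 with every library thinned, 2 in a fit of the 4 unedited libraries alone, and 309 in that fit with the word bis in the titles as a replicate block. The 2 libraries of each unedited group differ in title by that word only. Across 11864 genes the differences within the 2 pairs had a Pearson correlation of 0.0509.

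Cholesterol synthesis and heat shock genes, lower as sets in the knockout, also passed as lower in the electroporated cells, as did the glycolysis and hypoxia list, which did not pass in the knockout. Of 28 cholesterol synthesis genes 0 passed over all genes in the electroporated against WT cells (9 lower and 1 higher adjusted over the list alone), but the set did (camera, adjusted p = 1.3e-05, and adjusted p = 0.764 with an estimated correlation), with SQLE at a log2FC of -0.92 (0.086). Glycolysis and hypoxia genes (0 of 35, and 0 adjusted over the list alone) passed as a set (0.000135, and adjusted p = 0.764 with an estimated correlation), with ENO2 at -0.67 (0.0995). Heat shock genes (0 of 20, 1 lower adjusted over the list alone) passed lower (0.00433, and adjusted p = 0.825 with an estimated correlation), with BAG3 at -0.65 (0.113). Whether these sets differ in size of change between the 2 comparisons was not tested. The 2 electroporated libraries were not alike in these sets, as was looked at only afterwards. The median log2 difference from the WT mean was -0.23 in electroporated 1 and -0.84 in electroporated 2 for cholesterol synthesis, -0.50 and -0.30 for glycolysis and hypoxia, and -0.75 and 0.24 for heat shock. The heat shock set was therefore lower in electroporated 1 alone. Lists of this comparison were not run with a library left out.

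Cell cycle lists passed as lower in the electroporated cells, but only electroporated 1 was lower, with a median log2 difference from the WT mean of -0.70 for G2/M and -0.49 for G1/S, against 0.05 and 0.14 in electroporated 2. The G2/M list (0 of 53, and 0 adjusted over the list alone) passed with an adjusted p of 6.29e-05 and a median log2FC of -0.29, and the G1/S list (0 of 46, and 0 adjusted over the list alone) with 0.00304 and -0.20. With an estimated correlation their adjusted p were 0.901 and 0.921. Genes of immature thymocytes (0 of 18, 8 lower adjusted over the list alone) passed with 0.00433 (adjusted p = 0.619 with an estimated correlation) and a median of -1.19, lower in both electroporated libraries (-1.35 and -0.89). RAG1, which encodes a recombinase of antigen receptor genes, had 549 ± 593 in the electroporated cells, where its values were 130 and 968, and 3702 ± 66.7 in WT (0.125). T-cell surface molecules (1 of 26 lower, 6 adjusted over the list alone) passed with 0.0096 (adjusted p = 0.764 with an estimated correlation), and the costimulatory receptor gene CD28 fell from 3186 ± 304 to 700.4 ± 311 (0.0198). Notch genes (1 of 31 lower, 4 adjusted over the list alone) passed lower with 0.0154 (adjusted p = 0.764 with an estimated correlation), and HES1 fell by 2.52 on the log2 scale (0.0459). Cilium genes (2 of 49 lower, 5 adjusted over the list alone) passed lower with 0.0142 (adjusted p = 0.764 with an estimated correlation), with CEP164 at -0.94 (0.0363) and list medians of 0.01 and -0.19 in electroporated 1 and 2. The Xq22 neighbours (3 of 17 lower, 6 adjusted over the list alone) passed lower with 0.00144 (adjusted p = 0.619 with an estimated correlation), TCEAL3 falling from 137 ± 4.59 to 10.8 ± 5.08 (0.00514). The calls of CD28, HES1, CEP164 and TCEAL3 were lost without WT 1 and without WT 2. Those of CD28, HES1 and CEP164 were also lost without knockout 1 or knockout 2, those of HES1 and CEP164 without knockout 3, and that of HES1 without electroporated 1, with adjusted p of 0.052 to 0.39 over these fits.

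The other 4 lists passed as higher in the electroporated cells. T-cell receptor signalling genes (0 of 37, and 0 adjusted over the list alone) passed with 0.0114 (adjusted p = 0.733 with an estimated correlation), and LCP2 had a log2FC of 0.51 (0.0988). Transcription factors of T-ALL (2 of 41 lower, 2 lower and 4 higher adjusted over the list alone) passed with 0.00211 (adjusted p = 0.619 with an estimated correlation) and a median of 0.29, although the 2 called members fell, BCL11A with a log2FC of -2.73 (0.00233) and NKX2-1, with 0 reads in the electroporated libraries, by at least 20.2-fold (0.0486). Interferon-stimulated genes (1 of 46 higher and 1 lower, 2 and 1 adjusted over the list alone) passed with 0.00281 (adjusted p = 0.764 with an estimated correlation), with MX2 at 1.33 (0.0336) and OAS3 at -0.79 (0.0286). Cytoplasmic ribosomal protein genes (0 of 79, and 0 adjusted over the list alone) passed with 0.00281 (adjusted p = 0.901 with an estimated correlation) and a median of 0.11. Their median log2 difference from the WT mean was 0.19 in electroporated 1 and 0.03 in electroporated 2, and that of receptor signalling genes was 0.15 and 0.04. For the transcription factors it was 0.33 and 0.17, and for interferon-stimulated genes 0.35 and 0.24. The calls of BCL11A, NKX2-1, MX2 and OAS3 were lost without WT 1 and without WT 2, those of NKX2-1, MX2 and OAS3 also without knockout 1 or knockout 2, and those of MX2 and OAS3 without knockout 3, with adjusted p of 0.056 to 0.367. In all, 14 of 33 lists passed in this comparison, 4 higher and 10 lower, and 0 with an estimated correlation. The other lists had adjusted p of 0.0957 to 0.98.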

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

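The thinning to the shallowest library, the fit without abundant genes that vary over 4-fold within a group, and the list tests under same-total scaling were chosen only after the data were seen. No named gene that passed changed sign, and no list that passed changed the direction of its set test, under any alternative run for it. Signs were followed for the named genes only, not for every called gene. Among results without a call, BEX4 went from a log2FC of -0.10 to 0.11 without knockout 3, and the medians of several lists changed sign, such as the Xq22 neighbours (0.15, and -0.06 against WT), interferon genes (-0.07, and 0.03 under same-total scaling), ribosomal proteins (-0.06, and 0.04 under same-total scaling) and G1/S genes (-0.03, and 0.09 against the electroporated cells). The G2/M list, with a median of 0.02, passed as lower without electroporated 1 (median -0.15, adjusted p = 0.00654). Apart from the fits that leave out 1 library, 61 counts of genes or lists stayed within 1.5 times their value, 3 rose above that and 7 fell below it. Named genes kept their side of the threshold in 2662 cases, gained a call in 65 and lost it in 103. Lists kept theirs in 153 cases, gained a call in 4 and lost it in 30, of which 25 were under the estimated correlation. In the knockout against all unedited cells BEX1 and BEX5 passed under all alternatives run, BEX5 with an adjusted p of at most 0.0395, and BEX2 passed under none (0.0598 to 0.685).

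A 2-fold minimum left 1314 genes in the knockout against all unedited cells and 839 against both controls, by its own construction. With each library thinned, 1032 genes passed against both controls and 46 in electroporated against WT. For the other changes the cause was not tested. In fits of 2 groups alone 4550 genes passed against WT and 2 in electroporated against WT. Electroporated against WT also gave 678 genes by DESeq2 and 309 with the replicate block (bis). With an estimated correlation 0 lists passed in the knockout against all unedited cells and 0 in electroporated against WT.

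Leaving out 1 library gave 1510 to 4637 genes against all unedited cells, 1607 to 5354 against electroporated cells, 519 to 4539 against WT, 453 to 3445 against both, 2 to 2009 in electroporated against WT, and 8 to 11 lists in the knockout against all unedited cells. The lists of electroporated against WT were not run in this way. Where 1 library of a group remained, it was assumed to vary like the other groups. Of the 3087 genes, edgeR kept 2935 (95.1%) and DESeq2 3061 (99.2%). Without the shallow knockout 3, 2123 genes passed, 2029 of them (65.7% of the 3087) among those called with it. The median log2FC of all genes was -0.02 as deposited, -0.04 with TMM and 0.08 under same-total scaling. Depth limits knockout 3, where 2544 genes had fewer than 10 reads, against 30 to 402 in the other libraries.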

Other observations

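Tests chosen only after their result was seen were that of BEX1 as a check of the labels, those of separate drift and of cell line history, all 3 tests of abundant genes that vary within a group, and the percentiles and gene families given here. Genes named in this part were chosen after their values were seen. The 2 electroporated libraries differed in stress response genes. Over 37 genes of the amino acid and integrated stress response the median log2 difference of electroporated 1 minus 2 was 1.22. This was above all 10000 random lists of similar level (percentile 100). The median of WT 1 minus 2 was 0.56, also at percentile 100. Genes of the random lists were drawn singly, whereas genes of 1 response can vary together, so the percentiles do not measure chance between libraries. TRIB3, a target of the transcription factor ATF4, had 9687 normalised counts in electroporated 1 and 1239 in electroporated 2, and CHAC1, another such target, 1747 and 67.5. No other list was tested between these libraries, although the medians of others, such as heat shock and G2/M genes, also differed between them. The recombinase genes RAG1 and RAG2 had 130 and 70.1 in electroporated 1, and 968 and 403 in electroporated 2. IL7R, the interleukin 7 receptor gene, had 69.5 and 477.

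A set of 14 genes was below 10 in both electroporated libraries and at least 30 in each of the other 5, and in 13 of them the WT mean was below the knockout mean. Among 21 genes silent in the knockout the WT mean was below the electroporated mean in 12. NYNRIN had 946 in the knockout, 9.63 and 8.71 in the electroporated libraries, and 49.1 and 69.6 in WT. GPC5, a glypican gene, had 738 in the knockout, 2.75 and 6.53 in the electroporated libraries, and 87.0 and 78.2 in WT. MTUS1 had 721, 6.19 and 7.26, and 109 and 100.3. TWIST1, a basic helix-loop-helix transcription factor gene, had 213, 8.94 and 7.26, and 47.5 and 85.2.

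All 35 splits of the 7 libraries into 3 and 4 were counted for the knockout against all unedited cells. Only 1, the real one, gave as many genes (3087), and 1 of 35 is the smallest share this count can reach. If the 7 libraries are independent, this argues against a chance split but does not exclude it. If each unedited pair counts as 1 unit, the 5 units make only 10 splits into 3 and 2, too few for a share under 0.05. The highest other split gave 1774 genes and set electroporated 2 and both WT libraries against the knockout and electroporated 1. This count does not measure how close electroporated 1 is to the knockout. By rank correlation with the 3 knockout libraries, WT 1 (0.960 to 0.967) and WT 2 (0.962 to 0.968) were closest. Electroporated 1 (0.955 to 0.959) and electroporated 2 (0.946 to 0.956) were less close. On the first 2 principal components, unlike by rank correlation, electroporated 2 (66.45 and -27.61) lay farther from WT than electroporated 1 (46.68 and 14.21). WT 1 lay at 38.69 and 4.575 and WT 2 at 35.73 and 7.157.

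BEX2 mRNA was still present in the knockout libraries, and BEX5 mRNA was higher. For BEX2 a partial loss is not excluded, since its log2FC was -0.47, and -0.75 without electroporated 2. An unedited library mislabelled as knockout would have BEX1 within the unedited range, but the highest knockout value was 0.242 times the lowest unedited one. This check covers BEX1 only, so it cannot show whether BEX2 and BEX5 were edited. Reads borrowed from identical stretches of other annotated transcripts are argued against by the sequence. Of the 50-base stretches, 0% for BEX5 and 2.38% for BEX2 (shared with BEX1 and BEX4) lie in transcripts of another gene. Only exact matches to GENCODE transcripts were counted, so near matches and loci outside that annotation are not covered. Edits that alter the reading frame may leave the mRNA in place, and this stays open because gene counts hold no bases. Whether the rise of BEX5 follows from the edits was not tested.

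In the knockout 21 genes were below 10 in all 3 libraries and at least 30 in each unedited one, among them TNFSF8, NPM2, PTPRG, ANGPTL2 and CYP2J2, and 5 were ZNF genes (377 of 11620 eligible genes are). Deletions that reach the nearest tested gene are argued against, since 0 of 21 neighbours had a knockout mean under 0.25 times the unedited mean (median ratio 1.08). Separate drift of each knockout line is argued against too, with 2 genes silent in 1 of the deep knockout libraries alone. The unedited electroporated cells held 14 silent genes of their own, so a history of the cell lines apart from the knockout, such as shared descent, may account for such silencing. An effect of the knockout itself stays open and was not tested.

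Of the genes with a mean of at least 200 in a group, 134 varied over 4-fold between 2 of its libraries. Counting noise of the shallow library is argued against as the whole cause, since 111 of them varied between 2 deep libraries. Genes with further copies in the assembly may account for part. Of 133 with a position 8 lay in the MHC (chromosome 6, 28 to 34 Mb) or the pseudoautosomal region (X up to 2.8 Mb), or 6.02% against 0.325% of other genes (odds ratio 19.6, Fisher's exact 2-sided p = 4.2e-08). Only these 2 regions were counted, so the size of that part was not measured. Other varying genes also lie close together, such as LY6E, GSDMD, NAPRT, EEF1D, HSF1, CPSF1 and C8orf33 on chromosome 8 (143018529 to 145056030), and were not tested. Of the 78 that varied between the electroporated libraries, 7 were among 34 eligible stress response genes (odds ratio 35.7, Fisher's exact 2-sided p = 6.49e-09). All 7 were higher in electroporated 1, as were 57 of the 78. Both Fisher tests count genes as independent, which members of 1 region or 1 response may not be. A difference in stress response between these 2 libraries may account for part. Over the 37 listed genes the median log2 difference from the WT mean was 0.77 in electroporated 1 and -0.43 in electroporated 2. This difference therefore cannot be assigned to electroporated 1 alone. The rest is unexplained, and no biological explanation from the groups was tested.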
